A study of Homo sapiens with 16 samples.

How the data were processed

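Messenger RNA levels were measured in the human breast cancer line MDA-MB-231 (labelled WT) and in a derivative of it named COGDR-5. Per the labels' protocols, quadruplicate dishes of each were left to attach overnight in normoxia with high glucose and then stayed untreated or spent 8 h in 0.2% oxygen. Total RNA was depleted of ribosomal RNA, converted to biotin-labelled target and hybridised to 16 Affymetrix whole-transcript arrays, 4 per group. The labels do not say whether the 4 samples of a group came from cultures grown apart, so p-values measure the spread between these samples, which may be technical.

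The values are log2 intensities as the authors deposited them, 1 per probe and array. The log2 scale was read from the values, which ran from 2.90 to 13.95 with similar medians on all 16 arrays. The submitters' processing notes name Partek. Its version, the background correction, the normalization and the summary of probes are not given in the sources used here. Values were used without further normalization. Of 21980 probes, 14432 were paired with 1 gene symbol, 2408 with several and 5140 with none in the annotation table used. Only probes with 1 symbol were named. Where 197 symbols had more than 1 probe, the probe with the highest mean over all arrays was kept, which left 14232 genes. The table has no detection calls. After the data had been seen, the 95th percentile of 220 olfactory receptor genes on each array was taken as background (5.72 to 6.67). The means of 10791 of the 14232 genes lay below its average over the arrays. Where a called gene was not above it on any array of the lower group, its fold is given as at least that of the higher group over this percentile or the measured signal, whichever was higher on each array. The Entrez identifiers of 14404 probes were found in the RefSeq gene table of assembly GRCh38.p14, which served only for gene names and for the order of genes along chromosomes.

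All 5 comparisons came from 1 model over the 16 arrays with a mean per group, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. They were COGDR-5 against WT in normoxia and in hypoxia, hypoxia against normoxia in WT and in COGDR-5, and the difference of the 2 hypoxia responses. P-values were two-sided, adjusted after Benjamini and Hochberg, with a threshold of 0.05. The number of arrays limits the precision: the median standard error was 0.22 on the log2 scale, with a 95% interval of ± 0.46. On simulated data for hypoxia against normoxia in WT with 14232 genes, 6% of changes of 0.5 on the log2 scale were called, 55.4% of changes of 1 and 94.8% of changes of 2, with 82 false calls among 140320 unchanged genes. The simulated noise was drawn independently for each gene and array, without the unequal array spread of the real data. These shares therefore need not hold for the real arrays.

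Before the data were examined, 23 gene lists were fixed. They covered glycolysis, other targets of hypoxia-inducible factors (HIF), nuclear subunits of the respiratory chain, pyruvate entry and the TCA cycle, mitochondrial biogenesis, mitochondrial ribosomal proteins, fatty acid oxidation, glutamine and amino acid supply, antioxidant and pentose phosphate genes, breast tumor-initiating cell markers, mesenchymal genes, epithelial genes, the unfolded protein and integrated stress response, proliferation, interferon-stimulated genes, NF-kB and inflammatory genes, cholesterol synthesis, and autophagy. Markers of luminal breast, leukocyte, melanocytic, and endothelial and fibroblast cells stood for other cell types. A list of mitochondrial genome transcripts had fewer than the 3 measured members a test needed, so 22 lists were tested. The test was camera with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it.

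Genes were named by a rule also set before the data were examined. It took, per comparison, up to 10 of the highest and 10 of the lowest log2 differences among called genes whose 2 groups did not overlap, up to 4 members by smallest p from each list past the threshold and up to 2 from the others, and a fixed set of hypoxia, metabolism and stem cell genes. Of the fixed set, CA9 was not among the tested genes. Alternatives were quantile normalization, centring on medians, leaving out genes dimmer than the median gene, averaging the probes of a gene, other variance models, a block of runs of sample titles, other thresholds, only the arrays compared, and leaving out each array. Array weights, equal array spread, cyclic loess, leaving out 2 doubtful arrays, all probes, main effects over both conditions or cell types, and runs of 30 to 59 neighbouring genes were added after seeing the data. Counts were also repeated over the 35 splits of 8 arrays into 4 and 4, or over 100 regroupings of residuals for the difference of responses. Plots were drawn with matplotlib.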

Results

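Gene expression was profiled in MDA-MB-231, a triple-negative human breast cancer line, and in its derivative COGDR-5, with and without 8 h of hypoxia at 0.2% oxygen. The series concerns mitochondrial metabolism of tumor-initiating cells when oxygen and glucose are short. Each of the 4 groups held 4 arrays, which limits the precision. The arrays differed in the spread of their values. The standard deviation over all 21980 probes ran from 1.05 on WT hypoxia replicate 3 to 1.53 on WT hypoxia replicate 2. The first principal component of the arrays held 28.1% of the variance, and its scores correlated with this standard deviation by 0.992. No difference of the spread between groups was found in any of 4 comparisons, with exact permutation p-values from 0.486 to 0.743 (two-sided, all 0.743 after adjustment). With 4 arrays per group this test could miss a difference, so the spread may still affect the comparisons. Its means were 1.28 and 1.37 in WT and 1.27 and 1.31 in COGDR-5, in normoxia and hypoxia.

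**Figure D1:**
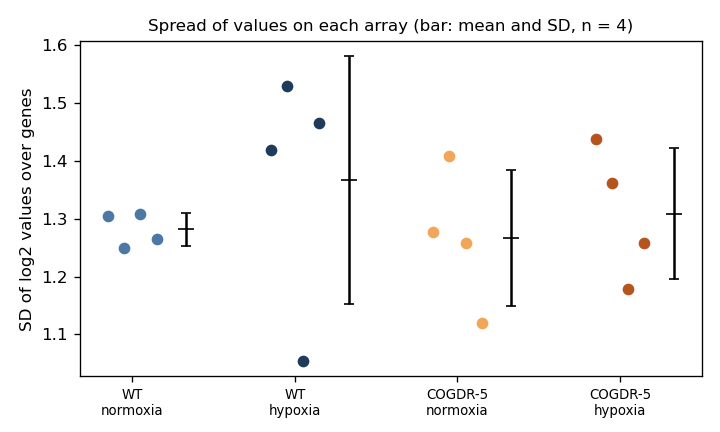
Spread of log2 values over all 21980 probes on each array (vertical axis, standard deviation) in the 4 groups (horizontal axis). Points are arrays and black bars the mean and SD of 4 arrays; WT hypoxia held both the narrowest array, at 1.05, and the widest, at 1.53.

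Hypoxia against normoxia in WT asked what oxygen loss changed in the parental line. Known HIF targets and glycolytic genes rose. NDRG1, a stress-induced HIF target, rose 5.93-fold (log2 2.57 ± 0.33 SE, n = 4 per group, limma adjusted p = 0.00406). ERRFI1, a feedback inhibitor of EGFR, rose 4.54-fold and NOG, a BMP antagonist, 3.92-fold, each from a level that 3 of the 4 normoxia arrays did not show above background. On all 4 normoxia arrays INSIG2, which retains the sterol sensor in the endoplasmic reticulum, LOX, the collagen crosslinking oxidase, and DDIT4, an inhibitor of mTORC1, were not above background, so they rose at least 1.51-fold, 2.78-fold and 1.46-fold. INSIG2 and DDIT4 were each also not above background on 1 of the 4 hypoxia arrays, so their bounds are less secure. Background here is the 95th percentile of 220 olfactory receptor genes on each array, as the table has no detection calls. Log2 differences are those of the measured signals throughout, and for genes near background they give no exact ratio of RNA.

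Of 14232 genes, 18 passed an adjusted p of 0.05 with limma, 15 higher and 3 lower, and 1338 had an unadjusted p under 0.05 against 712 from chance. The 3 that fell were the histone gene H2BC14 (log2 -2.12 ± 0.35 SE), FOXJ1, a regulator of motile cilia (-1.42 ± 0.24), and SLIRP-OT1 (-1.28 ± 0.20). FOXJ1 and SLIRP-OT1 were not above background on any hypoxia array, so they fell at least 2.22-fold and 1.56-fold. In the glycolysis list, 17 of 18 measured members were higher, with a median of 0.74. Of these, 5 were called over all genes and 10 adjusted over the list alone. PFKFB4 (1.43 ± 0.20) and PFKFB3 (1.42 ± 0.25), which set the level of the phosphofructokinase activator, rose. So did HK2, which phosphorylates glucose (1.75 ± 0.31), PDK1, which blocks pyruvate dehydrogenase (1.46 ± 0.24), and LDHA, which makes lactate (1.17 ± 0.20). PDK1 and PFKFB4 were not above background on any normoxia array or on 1 of the 4 hypoxia arrays. Their rises of at least 1.19-fold and 1.37-fold are therefore bounds that are not secure. HK2 was not above background on 3 of the 4 normoxia arrays, and PFKFB3 on 2. Camera placed the list above other genes (adjusted p = 6.81e-19). With an estimated correlation the adjusted p was 0.083, but 0.000107 at equal array spread, 0.000967 with quantile normalization, 5.65e-05 with cyclic loess and 0.0326 without 2 doubtful arrays (WT hypoxia replicate 3 and COGDR-5 normoxia replicate 4). The median was 0.32 with cyclic loess and 1.12 without the 2 arrays.

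Among the other HIF targets, 28 of 31 were higher, with a median of 0.86, and 7 were called over all genes and 20 adjusted over the list alone. Camera gave an adjusted p of 7.84e-27 (adjusted p = 0.0201 with an estimated correlation). A further 5 lists passed camera at the preset correlation. Members were higher for pyruvate entry and the TCA cycle in 16 of 19 (DLD 1.07 ± 0.32, PDHB 0.66 ± 0.22; none called; adjusted p = 0.0074; adjusted p = 0.547 with an estimated correlation). For fatty acid oxidation they were higher in 12 of 16 (HADHA 0.97 ± 0.32; 0 called, also adjusted over the list alone; adjusted p = 0.0074; adjusted p = 0.083 with an estimated correlation). Glutamine and amino acid supply had 10 of 13 higher (SLC38A2, a glutamine carrier, 0.96 ± 0.34; 0 called; adjusted p = 0.0074; adjusted p = 0.547 with an estimated correlation). Proliferation had 19 of 23 higher and 1 called, CCNE2 (0.83 ± 0.15), a cyclin of the entry into S phase (adjusted p = 0.00228; adjusted p = 0.581 with an estimated correlation). CCNE2 was not above background on any normoxia array or on 2 of the 4 hypoxia arrays. Autophagy and mitophagy had 9 of 15 higher; 1 was called, the mitophagy receptor BNIP3L (1.35 ± 0.25), and 2 adjusted over the list alone (adjusted p = 0.0074; adjusted p = 0.199 with an estimated correlation). BNIP3L was not above background on 3 of the 4 normoxia arrays. BNIP3L and BNIP3 (2.47, limma adjusted p = 0.424) also belong to the other HIF targets, so these lists are not independent. At the preset correlation with the arrays at 1 spread, proliferation and glutamine supply no longer passed by any of 3 methods (adjusted p from 0.0975 to 0.33 and from 0.0619 to 0.143). Pyruvate entry and the TCA cycle failed at equal array spread (0.109) and with quantile normalization (0.12), and autophagy at equal array spread (0.059). Without the 2 doubtful arrays the medians were larger, 0.59 for proliferation (0.285 with all arrays), 0.54 for glutamine supply (0.33) and 0.45 for pyruvate entry and the TCA cycle (0.21).

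The respiratory chain list was split, 29 of 56 members higher and 27 lower, with a median of 0.03 and 0 called (adjusted p = 0.208). Median log2 differences in the remaining lists, none past the threshold, were 0.07 for mitochondrial ribosomal proteins, -0.03 for mitochondrial biogenesis, 0.17 for antioxidant genes, 0.05 for tumor-initiating cell markers, -0.10 for mesenchymal and -0.16 for epithelial genes. They were 0.07 for the unfolded protein response, -0.04 for interferon-stimulated genes, -0.06 for NF-kB genes and 0.05 for cholesterol synthesis. Markers of luminal (-0.17), leukocyte (-0.07), melanocytic (-0.14), and endothelial and fibroblast cells (-0.07) did not pass either. HIF1A itself stood at -0.69 (adjusted p = 0.437), VEGFA at 1.01 (adjusted p = 0.246) and CD44 at 0.13 (adjusted p = 0.891). The count was 227 without WT hypoxia replicate 3. It was 10, 7, 4 and 3 without WT normoxia replicates 1, 2, 3 and 4, and 7, 5 and 5 without WT hypoxia replicates 1, 2 and 4. INSIG2 passed in all 21 alternatives run, NDRG1 and ERRFI1 in 20 each and PFKFB4 in 19, whereas LDHA passed in 7, not with cyclic loess or equal array spread (log2 from 0.04 to 1.34 and adjusted p from 0.000321 to 0.948 over its alternatives). Among other called genes, H2BC14 passed in 14, DDIT4, HK2 and CCNE2 in 13 each, FOXJ1 in 12 and BNIP3L in 11. At least 7 lists, the number found, came from 12 of the 35 splits of these 8 arrays into 4 and 4.

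**Figure D2:**
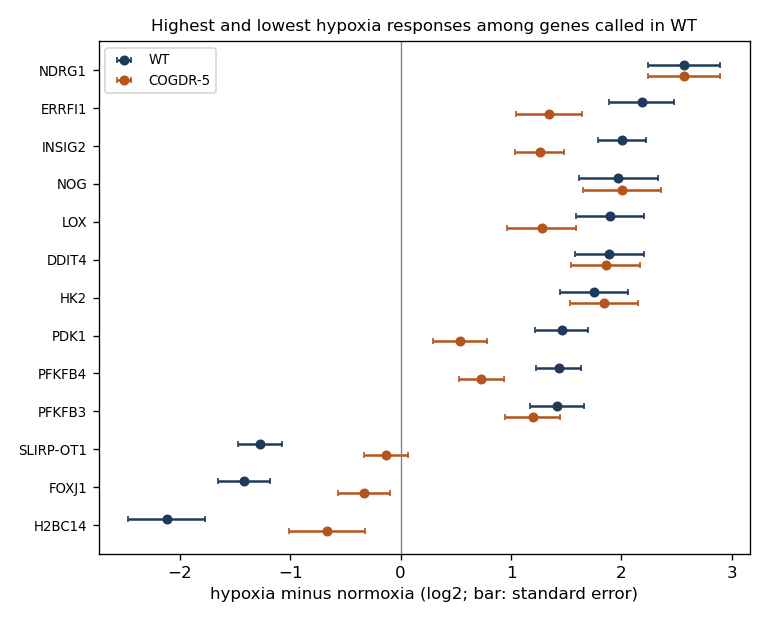
Log2 difference between hypoxia and normoxia (horizontal axis, bars are standard errors) in WT (dark blue) and COGDR-5 (orange) for the highest and lowest log2 differences among the genes called in WT. NDRG1 stood at 2.57 in WT and 2.56 in COGDR-5; the genes were chosen on the WT arrays, which favours larger values there.

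Hypoxia against normoxia in COGDR-5 put the same question to the derivative. NDRG1 rose 5.92-fold (log2 2.56 ± 0.33 SE, n = 4 per group, limma adjusted p = 0.00824) and was the only gene called; 544 genes had an unadjusted p under 0.05 against 712 from chance. HK2 (1.84 ± 0.31), DDIT4 (1.86 ± 0.31) and BHLHE40, a transcriptional repressor (1.22 ± 0.21), lay just beyond the threshold, each with an adjusted p of 0.0637. INSIG2 stood at 1.26 ± 0.22 (adjusted p = 0.0747).

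As lists, the hypoxia genes moved up. Other HIF targets were higher in 29 of 31 members, with a median of 0.66; 1 was called over all genes and 15 adjusted over the list alone (camera adjusted p = 1.6e-29; adjusted p = 0.0138 with an estimated correlation). Glycolysis had 17 of 18 higher and a median of 0.51, with 0 called over all genes and 5 adjusted over the list alone, among them HK2, PFKFB3 and the glucose transporter gene SLC2A1 (1.26 ± 0.31; list adjusted p = 2.77e-14). With an estimated correlation the list's adjusted p was 0.262, and 0.22 without the 2 doubtful arrays, but 0.000218 at equal array spread, 0.00151 with quantile normalization and 7.64e-05 with cyclic loess, where the median was 0.24. Glutamine and amino acid supply had 11 of 13 higher and 0 called (SLC38A2 0.92 ± 0.34; adjusted p = 0.00759; adjusted p = 0.694 with an estimated correlation; 0.208 at the preset one without the 2 doubtful arrays). The respiratory chain list again had a median near 0 (-0.03, 26 of 56 higher, adjusted p = 0.992). HMOX1, the haem oxygenase (0.88 ± 0.21), was called in the antioxidant list alone, and the chemokine gene CXCL8 (-1.14 ± 0.26) in the NF-kB list alone. HIF1A stood at -0.97 (adjusted p = 0.736). The count was 0 by limma without COGDR-5 normoxia replicate 1, COGDR-5 hypoxia replicate 1 or COGDR-5 hypoxia replicate 2, where NDRG1 no longer passed (adjusted p from 9.48e-09 to 0.202 over its alternatives). It was 3 without COGDR-5 normoxia replicate 4 and 2 without COGDR-5 hypoxia replicate 4. With quantile normalization, equal array spread or cyclic loess 11 genes were called, all higher, with 750, 751 and 749 at an unadjusted p under 0.05. As large a gene count came from 4 of 35 splits, and as large a list count from 15.

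COGDR-5 against WT in normoxia asked how the derivative differed before treatment. MMP1, MMP3 and IL1B, which encode an interstitial collagenase, stromelysin-1 and the cytokine interleukin-1 beta, were higher in COGDR-5. None was above background on any WT normoxia array, so the folds are lower bounds. MMP3 was also not above background on 2 of the 4 COGDR-5 normoxia arrays, so its bound is not secure. IL1B was at least 2.64-fold higher (log2 difference of the signals 2.46 ± 0.31 SE, limma adjusted p = 0.00309), MMP1 at least 3.17-fold (2.42 ± 0.28, adjusted p = 0.0019) and MMP3 at least 1.19-fold (1.44, adjusted p = 0.00796). The mean of MMP1 was 5.53 ± 0.12 (SD, n = 4) in WT and 7.96 ± 0.68 in COGDR-5, and that of IL1B 5.23 ± 0.16 and 7.69 ± 0.71.

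These 3 were the genes called, with 624 at an unadjusted p under 0.05 against 712 from chance, and 0 of 22 lists passed camera, with the preset or an estimated correlation, or fry. In the NF-kB and inflammatory list, 8 of 17 members were higher and the median was -0.15; IL1B was called over all genes, and IL1B with IL1A, interleukin-1 alpha (1.52 ± 0.38), adjusted over the list alone. In the luminal list TFF3 (-0.85 ± 0.22) was lower adjusted over the list alone. TGFBI of the mesenchymal list stood at 1.19 ± 0.34 (adjusted p = 0.819). Medians were 0.08 for glycolysis, 0.06 for other HIF targets and -0.00 for the respiratory chain. The markers of leukocytes had a median of 0.11 and those of endothelial cells and fibroblasts of 0.06, without a call. MMP1 and IL1B passed in all 21 alternatives run, and MMP3 in 19, not without WT normoxia replicate 2 (adjusted p from 0.000992 to 0.0928 over its alternatives). CD44 stood at 0.16, CD24 at 0.27, PPARGC1A at 0.16 and TFAM at 0.21, each with an adjusted p of 0.999.

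**Figure D3:**
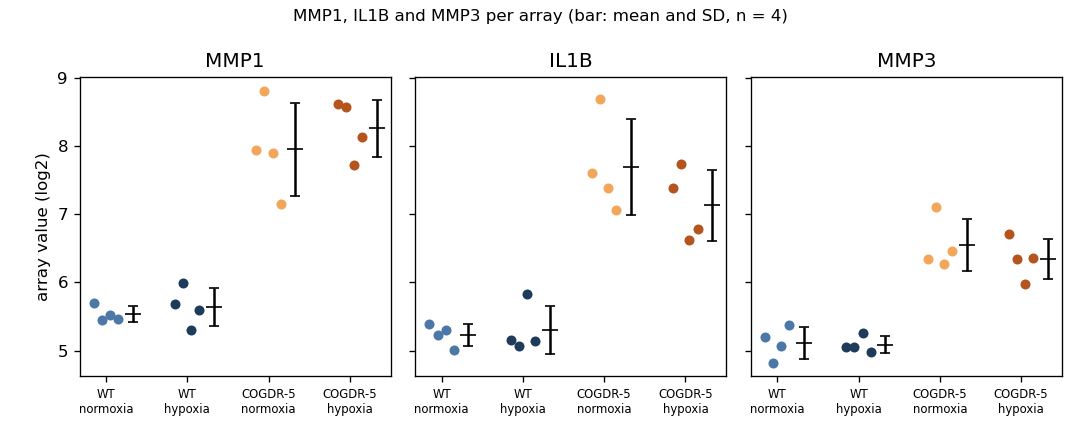
Log2 array values (vertical axis) of MMP1, IL1B and MMP3 in the 4 groups (horizontal axis). Points are arrays and black bars the mean and SD of 4 arrays; for MMP1 the means were 5.53 and 5.64 in WT and 7.96 and 8.26 in COGDR-5, in normoxia and hypoxia.

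COGDR-5 against WT in hypoxia gave MMP1 at least 4.34-fold higher (log2 difference of the signals 2.62, limma adjusted p = 0.000634) and MMP3 at least 1.15-fold higher (1.26, adjusted p = 0.0407), both not above background on any WT hypoxia array. MMP3 was also not above background on 1 of the 4 COGDR-5 hypoxia arrays, so its bound is not secure. MOS, a kinase of oocyte maturation, was lower (-1.37, adjusted p = 0.0407), from means of 5.83 ± 0.39 (SD, n = 4) in WT and 4.46 ± 0.09 in COGDR-5, but none of these 8 arrays showed it above background, so no fold is given. IL1B stood at 1.83 with an adjusted p of 0.0518 and IL1A at 1.71 with 0.258; both were called adjusted over the NF-kB list alone. The 3 called genes went with 861 at an unadjusted p under 0.05.

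Camera placed 4 lists lower in COGDR-5 at the preset correlation. Proliferation was lower in 21 of 23 members (CCNE2 -0.65 ± 0.15, MCM6 -0.72 ± 0.22), with 0 called over all genes and 2 adjusted over the list alone (adjusted p = 3.45e-05; adjusted p = 0.841 with an estimated correlation). Cholesterol synthesis was lower in 11 of 15 (DHCR7 -0.73 ± 0.23, INSIG1 -0.63 ± 0.21), with 0 called either way (adjusted p = 0.00173; adjusted p = 0.0498 with an estimated correlation, but 0.069 at equal array spread, 0.0599 with quantile normalization, 0.0573 with cyclic loess and 0.0942 without the 2 doubtful arrays). The respiratory chain was lower in 40 of 56, with 0 called and 1 adjusted over the list alone, the ATP synthase subunit gene ATP5PO (-1.48 ± 0.29; list adjusted p = 0.00813; adjusted p = 0.841 with an estimated correlation). Glycolysis was lower in 14 of 18 (PDK1 -0.66 ± 0.24), with 0 called either way and a median of -0.16 that became 0.00 at equal array spread and -0.44 without WT hypoxia replicate 3 (adjusted p = 8.21e-07 at the preset correlation). Without omissions its adjusted p was 0.00813, and 0.841 with an estimated correlation. The leukocyte marker list, with a median of 0.24, did not pass (camera adjusted p = 0.261; fry adjusted p = 0.293, unadjusted 0.0266). Without the 2 doubtful arrays the medians of proliferation and the respiratory chain were -0.54 and -0.34. At equal array spread only proliferation and cholesterol synthesis of these 4 passed the preset test, and 21 of 35 splits gave at least 4 lists. MMP1 passed in all 21 alternatives run, MMP3 in 11 of 21 and MOS in 11 of 20, and IL1B passed in 9 of 21. The 3 calls were 2 higher and 1 lower in COGDR-5, but most were lower in some settings: 5 higher and 45 lower without WT hypoxia replicate 3, 11 and 48 with array weights, and 6 and 69 without the 2 doubtful arrays. The gene count was 1 without WT hypoxia replicate 2, WT hypoxia replicate 4, COGDR-5 hypoxia replicate 2 or COGDR-5 hypoxia replicate 4.

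The difference of the hypoxia responses, COGDR-5 minus WT, asked whether the derivative responded otherwise. No gene was called: limma gave 0 of 14232 (smallest adjusted p = 0.495), with 558 at an unadjusted p under 0.05 against 712 from chance. The other settings run, each array left out in turn included, also gave 0, with 283 to 1794 genes at an unadjusted p under 0.05. The 283 came without the genes dimmer than the median gene, and the setting with all 21980 probes gave 829. The 712 from chance does not apply to these 2 settings. Among glycolytic genes PDK1 stood at -0.92 ± 0.34, PFKFB4 at -0.70 ± 0.29 and LDHA at -0.57 ± 0.28, each with an adjusted p of 1. Glycolysis was lower in 16 of 18 members, with a median of -0.20, and proliferation in 18 of 23, with a median of -0.25. Both passed camera at the preset correlation (adjusted p = 0.00816 for each; adjusted p = 0.7 with an estimated correlation for each). In glycolysis 0 members were called adjusted over the list alone, and in proliferation 1, CCNE2 (-0.83 ± 0.22). Neither list passed under quantile normalization, equal array spread or cyclic loess. Without the 2 doubtful arrays the medians were -0.705 for glycolysis and -0.61 for proliferation (adjusted p = 2.24e-08 and 1.28e-08; 0.329 for each with an estimated correlation), and 54 of 100 regroupings gave at least 2 lists.

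Across all 14232 genes the responses of the 2 cell types correlated with a Pearson r of 0.242 and a Spearman rho of 0.208, with a slope of 0.197, where genes are not independent replicates. With 1 array left out these ran from 0.144 to 0.323, from 0.108 to 0.294 and from 0.124 to 0.304, and without the 2 doubtful arrays the Spearman rho was 0.0345. The median standard error of a response was 0.22, above the median absolute changes of 0.188 in WT and 0.141 in COGDR-5. Such noise lowers the correlations and the slope over all genes. Over the 49 genes of the glycolysis and other HIF target lists the Pearson r was 0.88 and the slope 0.831, 46 had the same sign and 39 the larger change in WT. Of all 14232 genes, 8198 had the same sign and 8432 the larger change in WT. Over the 18 genes called in either cell type all 18 had the same sign, with a slope of 0.566; these genes were chosen mostly on the WT arrays, which lowers the slope.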

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

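The tests of explanations and the counts over splits given here were chosen after the results had been seen.

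Of 128 tests for 1 array far from the other 3 of its group, over 30 named genes and 2 array measures, 7 stood out, which is 5.47% where chance gives about 5%. In WT hypoxia replicate 3, IL1B was highest at 5.83 (nearest 5.16), and LOX at 6.78 (8.05), PFKFB4 at 6.20 (6.87) and VEGFA at 6.50 (7.74) were lowest. In WT normoxia replicate 4, VHL was lowest at 5.08 (nearest 5.44). The mean correlation with the other arrays was lowest at 0.746 for WT hypoxia replicate 3 (nearest 0.848) and at 0.781 for COGDR-5 normoxia replicate 4 (nearest 0.847). Among probes without a single gene symbol, 1 was higher in COGDR-5 in normoxia (log2 difference 2.56), 1 in hypoxia (2.9) and 1 higher in hypoxia in WT (2.15). The difference of the hypoxia responses had a median of -0.25 over the proliferation list, past camera at the preset correlation only: the adjusted p was 0.7 with an estimated correlation. At the preset one it was 0.292 with quantile normalization, 0.292 at equal array spread and 0.0563 with cyclic loess, but 1.28e-08 without WT hypoxia replicate 3 and COGDR-5 normoxia replicate 4, where the median was -0.61.

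At the preset correlation the glycolysis list was lower in COGDR-5 than in WT in hypoxia and rose less with hypoxia, with a median difference of the responses of -0.20, but neither passed with an estimated correlation (adjusted p = 0.841 and 0.7). Unequal array spread may account for its camera calls: with the arrays at 1 spread by 3 methods, the smallest adjusted p over both comparisons was 0.154. Omitting any 1 of 6 of the 16 arrays ended a call, while the p of the difference of responses was 2.67e-07 without WT hypoxia replicate 3 (median -0.50) and 0.552 without WT hypoxia replicate 2 (median -0.07), so the weight of single arrays stays open. A smaller glycolytic response of COGDR-5 stays open too: at equal spread the mean response differed by -0.18 ± 0.08 (SE), with a permutation p of 0.0298, or 0.179 adjusted over the 12 score tests run. With cyclic loess the difference was -0.16 ± 0.06 (permutation p = 0.0122, adjusted 0.147).

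MMP1, IL1B and MMP3 were higher in COGDR-5 in both conditions, though IL1B was not called in hypoxia (adjusted p = 0.0518, past the threshold in 9 of 21 alternatives). A single array does not account for this, since their smallest log2 difference with any array left out was 1.14. Leukocytes in the COGDR-5 cultures were examined by 11 markers. Their mean rose by 0.15 ± 0.05 (SE), with an upper 95% bound of 0.256 (CD74 0.40, LYZ -0.12). Fibroblasts in the COGDR-5 cultures were examined by 5 markers, with 0.08 ± 0.08 and a bound of 0.262 (LUM 0.36, COL1A2 -0.01). Both bounds lie far below 1.35, the smallest mean difference of the 3 genes. However, the mean levels of the markers were 5.83 for leukocytes and 5.2 for fibroblasts, within or below the background range of 5.72 to 6.67. A rise of such markers may be muted, so leukocytes or fibroblasts as the whole cause stay open. More copies of the wider segments that hold the genes are argued against by 9 neighbours above background, pooled over both segments. Their median was -0.0753 (95% interval -0.55 to 0.16). This interval came from resampling the 9 genes, so it leaves out the spread between arrays. IL1A, which is among the 9 neighbours and lies next to IL1B, rose by 1.61 ± 0.27 (SE, limma adjusted p = 0.0274). A gain of only the genes themselves and those next to them was therefore not tested. A regulatory difference of the derivative is another hypothesis that was not tested. The pattern was found and examined on the same data.

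For gene counts, the real grouping gave more called genes than any other split in 2 comparisons. COGDR-5 against WT in normoxia had 3 genes where the highest other split had 1. Hypoxia in WT had 18 where the highest other had 3. In each, 1 split of 35, the real one, gave as many. This is the smallest share that 35 splits can give, and it was not adjusted over the counts tested, so chance is not excluded. Chance cannot be excluded for the other counts above 0 either, where other groupings gave as many or more. For genes in COGDR-5 against WT in hypoxia, 2 of 35 splits gave at least 3 and the highest other gave 1050, which points to a structure of the samples: of the 35 splits it parts the arrays most by their spread (rank 1), and at equal array spread it gave 0. For hypoxia in COGDR-5, 4 of 35 gave at least 1 and the highest other 1. For lists, as many or more came from 21 of 35 between the cell types in hypoxia (real 4, highest other 11), 12 of 35 for hypoxia in WT (real 7, highest other 12) and 15 of 35 in COGDR-5 (real 3, highest other 13). For the difference of responses 54 of 100 regroupings gave at least 2 lists (highest other 13). Where the real count was 0 every split gives as many, so the 35 of 35 splits for lists in normoxia (highest other 6) and the 100 of 100 regroupings for genes of the difference of responses (highest other 475) test nothing.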

How the results depend on the processing

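Array weights, equal array spread, cyclic loess, the omission of 2 doubtful arrays (WT hypoxia replicate 3 and COGDR-5 normoxia replicate 4), all probes and the means over both conditions or cell types were chosen after seeing the data. No called gene changed its direction, and no called list did by its mean. The median of the glycolysis list between COGDR-5 and WT in hypoxia went from -0.161 to 0.00217 at equal array spread. In addition, 97 differences of named genes that were not called in either setting changed sign. Counts are given against the main counts of called genes: 3 for COGDR-5 against WT in normoxia, 3 in hypoxia, 18 for hypoxia in WT, 1 for hypoxia in COGDR-5, 8 for COGDR-5 against WT over both conditions and 25 for hypoxia over both cell types; of lists, 0, 4, 7, 3 and, for the difference of responses, 2. Counts not given stayed within 1.5 times. Except where stricter thresholds or fewer arrays or genes lower a count by construction, the cause was not tested.

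Quantile normalization gave 8 genes for COGDR-5 against WT in hypoxia, 11 for hypoxia in COGDR-5, 20 over both conditions and 47 over both cell types, and 2 lists between the cell types in hypoxia, 4 for hypoxia in WT and 0 for the difference of responses. Without the genes dimmer than the median gene there were 6 genes for hypoxia in COGDR-5 and 1 list between the cell types in hypoxia. A mean-variance trend with robust moderation gave 5 genes for COGDR-5 against WT in hypoxia and 5 for hypoxia in COGDR-5. No moderation gave 0 for the latter, with 553 at an unadjusted p under 0.05. An adjusted p under 0.01 left 1 gene for COGDR-5 against WT in hypoxia, 4 for hypoxia in WT, 4 over both conditions and 12 over both cell types. A 2-fold minimum left 16 over both cell types. Only the arrays compared gave 1 gene for COGDR-5 against WT in hypoxia and 1 for hypoxia in WT. An estimated correlation left 1, 1, 1 and 0 lists for COGDR-5 against WT in hypoxia, hypoxia in WT, hypoxia in COGDR-5 and the difference of responses; fry gave 1, 3, 1 and 0.

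Array weights gave 59 genes for COGDR-5 against WT in hypoxia, 559 for hypoxia in WT, 9 for hypoxia in COGDR-5, 96 over both conditions and 214 over both cell types, with 9 lists between the cell types in hypoxia and 5 for the difference of responses. Equal array spread gave 5 genes for COGDR-5 against WT in normoxia and 10 in hypoxia, 28 for hypoxia in WT, 11 in COGDR-5, 17 over both conditions and 48 over both cell types, with 2 lists between the cell types in hypoxia, 3 for hypoxia in WT and 0 for the difference. Cyclic loess gave 5, 14, 36, 11, 44 and 66 genes in the same order, with 2 lists between the cell types in hypoxia and 0 for the difference. Without the 2 doubtful arrays there were 75 genes for COGDR-5 against WT in hypoxia, 435 for hypoxia in WT, 10 in COGDR-5, 60 over both conditions and 122 over both cell types, with 1 list between the cell types in normoxia, 9 in hypoxia and 7 for the difference. The Spearman correlation of the responses was then 0.0345. With cyclic loess as well there were 7, 93, 290, 16, 77 and 168 genes. All probes gave 6 for hypoxia in WT.

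With 1 array left out, the counts of genes ran from 2 to 3 for COGDR-5 against WT in normoxia, from 1 to 50 in hypoxia, from 3 to 227 for hypoxia in WT, from 0 to 3 in COGDR-5, from 4 to 110 over both conditions, from 14 to 212 over both cell types and from 0 to 0 for the difference of responses. The lists ran from 0 to 0, 1 to 9, 4 to 10 and 2 to 4 in the first 4 of these, and from 0 to 6 for the difference. The Pearson correlation ran from 0.144 to 0.323, the Spearman correlation from 0.108 to 0.294 and the slope from 0.124 to 0.304. The sample titles form 4 runs, used as a block: this gave 1 gene for COGDR-5 against WT in hypoxia, MMP1, without MMP3 and MOS, and 3 for hypoxia in COGDR-5 and left the other counts within 1.5 times. Deviations of arrays of the same run correlated by 0.0605 on average (-0.218 to 0.431), against -0.0198 for different runs, and above 0.1 in 6 of 24 pairs. Of the 16 arrays, 8 matched their own run best, where chance gives 4. As most pairs lay below 0.1, the runs were not treated as a pairing, but these values leave it open whether arrays of a run share something.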

Other observations

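The means over both conditions or cell types, the histone genes, the runs of neighbouring genes and their tests were chosen after seeing the data, and genes named here lie outside the rule for named genes where only these means called them.

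Averaged over both cell types, hypoxia called 25 genes with limma, 21 higher and 4 lower. CCNE2 and SLIRP-OT1, called in WT, were not among them, while genes not called in WT included P4HA1, a collagen prolyl hydroxylase (log2 1.53 ± 0.26 SE, adjusted p = 0.0194), the glucose transporter gene SLC2A1 (1.35 ± 0.22), VLDLR, a lipoprotein receptor (0.82), TMEM45A (0.80), WSB1 (0.73), MOB3A (1.07) and ARL6IP5 (0.68). LDHA was called at 0.88 but stood at 0.31 with cyclic loess (adjusted p = 0.654). The 4 lower genes were FOXJ1 (-0.87) and the histone genes H2BC14 (-1.39), H1-2 (-0.99) and H2AC6 (-0.63). The count was 212 without WT hypoxia replicate 3 and 14 without WT hypoxia replicate 4. Of 54 measured histone genes 42 were lower in hypoxia, with a median of -0.30 (WT -0.37, COGDR-5 -0.14) and 3 called. Camera gave an unadjusted p of 9.2e-09, and 0.000201 with an estimated correlation. At equal array spread 39 were lower and with cyclic loess 42. The list was formed because its members had been seen to fall, so this is not independent evidence.

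Averaged over both conditions, 8 genes differed between COGDR-5 and WT. MMP1 (2.52 ± 0.20 SE), IL1B (2.15 ± 0.22), IL1A (1.61 ± 0.27, adjusted p = 0.0274), MMP3 (1.35 ± 0.14) and CLDN11, a tight junction gene (1.18 ± 0.15), were higher. BAG3, a co-chaperone (-0.81), GNA11, a G protein subunit (-0.81), and CHCHD3, of the inner membrane organising complex of mitochondria (-1.03 ± 0.16), were lower. The balance of 5 higher and 3 lower was not stable: 16 were higher and 94 lower without WT hypoxia replicate 3, 16 and 80 with array weights, 15 and 45 without the 2 doubtful arrays (that one and COGDR-5 normoxia replicate 4), and 20 and 24 with cyclic loess. The count was 4 without any 1 of WT normoxia replicate 3, COGDR-5 normoxia replicate 3, WT hypoxia replicate 1 and COGDR-5 hypoxia replicate 4.

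Runs of 30 to 59 neighbouring genes shifted together between COGDR-5 and WT: of 463 runs, camera called 66 in normoxia and 11 in hypoxia at the preset correlation, and 0 and 1 with an estimated correlation. Array spread may account for part of the calls and stays open: at the preset correlation 9 of the 11 stayed called in all 3 settings with 1 spread, and 48, 43 and 35 of the 66 at equal spread, quantile normalization and cyclic loess, but with an estimated correlation these settings called 0 in either condition. A change of gene dosage of whole segments could give such runs and stays open, since 9 of the 11 had the same sign in normoxia (exact binomial p = 0.0654) and the medians correlated across runs by 0.154, below the highest of 100 shuffled gene orders, 0.188. As many runs came from 2 of 35 splits in normoxia (highest other 109) and from 2 of 35 in hypoxia (highest other 15), so chance cannot be excluded. Called runs alone do not point to gene dosage either, since the same preset test called runs between hypoxia and normoxia within WT. There it called 6 in the main setting, 57 at equal array spread, 30 with quantile normalization and 26 with cyclic loess. Within COGDR-5 it called 0 in each of these settings.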
